A study of Mus musculus with 3 samples.

How the data were processed

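EZH2, the catalytic subunit of polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse bone marrow-derived macrophages. Per the labels, marrow cells of C57BL/6 mice were grown into macrophages in medium with M-CSF, and were left untreated (NT) or given lipopolysaccharide (LPS) for 2 h. There were 3 samples, which were 1 EZH2 library per condition and 1 input DNA library, so no condition had a replicate. The condition of the cells behind the input DNA is not given in the labels, and no intervals of the input were used here. Per the labels, a service company prepared the chromatin and carried out the ChIP-seq with an EZH2 antibody.

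The submitters' processing notes name BWA, SICER and the genome build mm10, with no version and no role for each. BWA is a read aligner, and SICER finds broad enriched islands by pooling neighbouring windows. The deposited track file held 5 tracks, which were a track of intervals and a track of summits for each EZH2 library, and a track of merged regions. Start and end positions were deposited by the authors as BED coordinates, counted from 0, and are printed here 1-based on mm10. The deposited score of each interval is the authors' value at its summit, called the summit value below. All summit values were whole numbers, and their unit is not given in the sources used here. Read depth, duplicate removal, use of the input, scaling between libraries and the SICER settings are not given there either. Intervals were listed per library, and the merged regions covered exactly the union of both lists, 9785 regions over 17602.2 kb. Because scaling and depth are unknown, a lower summit value or a shorter interval list in a library cannot be read as less EZH2 on the chromatin. SICER joins windows into broad islands, so an interval can take in several neighbouring promoters, and genes of a cluster share intervals.

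The stimulated track carries TLR in its name where the labels say LPS. It was assigned to the LPS sample because LPS is a ligand of a Toll-like receptor (TLR) and this was the only stimulated EZH2 sample. This assignment is a limit on every value given for the LPS library.

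Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives the start and end of each gene without strand, exons or sequence. The planned windows around transcription start sites were therefore replaced by windows of 2.5 kb on each side of either annotated gene end, so that part of the intervals counted for a gene can lie at its 3' end. Planned measures of exons, introns, GC and CpG content and repeats were not analysed here, and random lists could not be matched on promoter CpG content. Overlap of the lists was computed with bedtools 2.31.1 at a minimum of 1 bp, with the Jaccard index of covered bases. For comparison, each list was shuffled 100 times within the annotated span of each chromosome. Wilson intervals at 95% are given for shares. They cover counting error only and treat neighbouring intervals as independent.

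The 17 gene lists were fixed before the data were examined. They were Hox cluster genes, developmental transcription factors outside the Hox clusters, developmental signalling ligands and antagonists, cyclin-dependent kinase inhibitors, polycomb and related chromatin genes, macrophage identity genes, early LPS response genes, late LPS and interferon response genes, negative regulators of inflammatory signalling, TLR and cytokine receptor signalling genes, alternative activation genes, T, B and NK lymphocyte genes, neutrophil and mast cell genes, erythroid and megakaryocyte genes, stromal and endothelial genes, neuronal genes, and housekeeping genes. Of their 483 genes, 3 are not protein-coding in the gene table and were left out. Each count was placed among 10000 random lists of the same size drawn from all protein-coding genes. The percentile describes these libraries and is no p-value, since genes are not replicates.

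The genes named were set by a rule fixed before the data were examined. It takes Socs3, the up to 4 members of each list with most covered bases, the 8 highest summits of each library with the nearest protein-coding gene, the 8 genes with the highest interval found in 1 library alone and no interval of the other within 10 kb, and the 8 highest and 8 lowest ratios of LPS to NT summit value among the merged regions at or above the median of the mean summit value. Predicted genes were passed over in the last 3 parts. The rule gave 105 genes, of which the text names a part, some others are not reported here, and genes outside it are marked as chosen after their values were seen.

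With 1 library per condition no test between conditions was possible, and values are given without p-values. Alternatives tried were 1 kb and 5 kb windows, the gene body plus 2.5 kb, intervals merged when under 2 kb apart, intervals at or above the median summit value, an overlap of at least 50% of the interval, and the NT list cut to the length of the LPS list by summit value. After the data were seen, random lists matched on gene length, 13 gene families defined by their symbols, and lists matched on NT summit value or on summit value and width were added. The counting and matching steps were tested on simulated data. All planted overlaps were found (100%), 5 of 100 null lists of 30 genes lay outside the central 95% of random lists, and 100 of 100 lists planted at 3 times the background share lay above it. In the matched medians 4 of 40 null lists lay outside. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.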

Results

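EZH2 occupancy was compared between untreated mouse bone marrow-derived macrophages (NT) and the same kind of cells after 2 h of LPS, a bacterial cell wall component that activates Toll-like receptor 4. EZH2 deposits the repressive H3K27 methylation mark. There was 1 EZH2 library per condition, so none of the differences below has a replicate check, and the read depth of both libraries is unknown. The NT library had 9643 intervals over 16926.9 kb, with a median width of 1305 bp and summit values from 11 to 253 (median 27). The LPS library had 4651 intervals over 9102.65 kb, with a median width of 1472 bp and summit values from 7 to 100 (median 16).

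Among the 8 highest summits of NT were those at the transcription factor genes Sp9 (summit value 253), Tlx2 (213), Pou3f1 (210), Foxl2 (202), Hoxa13 (193) and Hic1 (185) and the polycomb gene Bmi1 (198). Among the 8 highest of LPS were those at Foxl2 (93), Sp9 (92), Lbx1 (91), Sall3 (89), Nkx2-3 (87), Pou3f1 (87) and Slc30a3 (85), a zinc transporter gene. An interval over the higher-coordinate end of the non-coding RNA gene Malat1 ranked 2 in NT (226) and 1 in LPS (100). In NT it spanned 5802476 to 5804322 on chromosome 19 (mm10).

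The first comparison asked how far the intervals of NT and LPS coincided. Of the 4651 LPS intervals, 4375 (94.1%, 95% Wilson interval 93.3 to 94.7%) met an NT interval, against a mean of 1.49% after shuffling. Of the 9643 NT intervals, 4161 (43.2%, 42.2 to 44.1%) met an LPS interval, against 0.714% after shuffling. NT intervals with no LPS partner numbered 5482, with a median summit value of 23 and width of 1083 bp, and those with a partner had medians of 36 and 2019 bp. LPS intervals with no NT partner numbered 276, with medians of 11 and 912.5 bp. The Jaccard index of covered bases was 0.479.

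**Figure D1:**
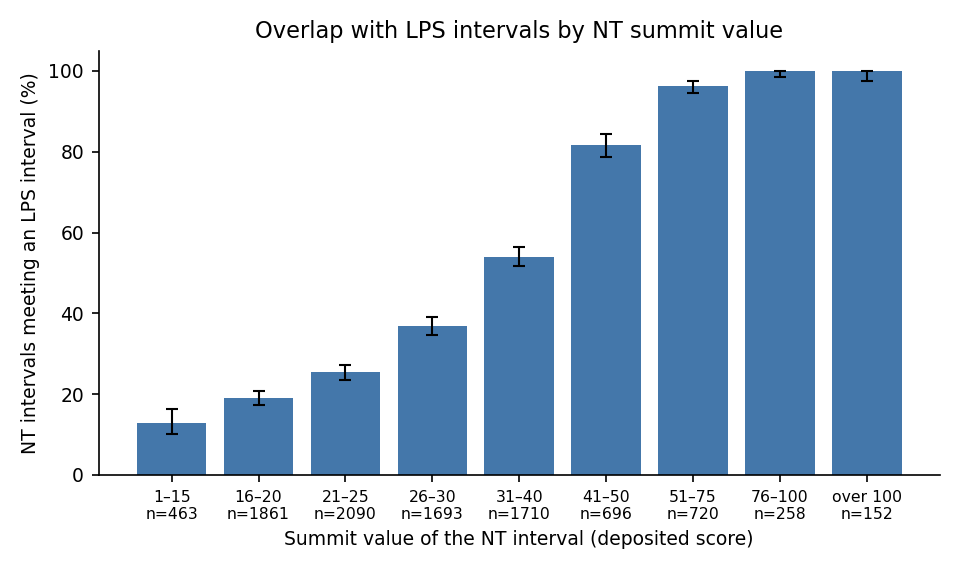
Bars give the percent of NT intervals that met an LPS interval by at least 1 bp, grouped by the NT summit value, with n intervals per group and 95% Wilson intervals as error bars. The share was 54.0% for NT summit values over 30 and up to 40, 96.3% over 50 and up to 75, and 100% above.

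The share of NT intervals with an LPS partner went with the NT summit value. It was 17.8% of 2324 intervals with a value up to 20 and 96.3% of 720 intervals over 50 and up to 75. All 410 NT intervals over 75 met an LPS interval (95% Wilson interval 99.1 to 100%). At like NT summit value the share also went with width. Over 30 and up to 40, 40.8% of NT intervals under 2 kb and 88.5% of those at 2 kb or wider had an LPS partner. These shares were 65.2% and 96.7% over 40 and up to 50, and 81.2% and 99.7% over 50 and up to 75. The groupings by summit value and by width were chosen after the data were seen. In the 4027 merged regions with an interval in both libraries, the median ratio of LPS to NT summit value was 0.5, with the central 95% of regions between 0.282 and 0.824, and 11 regions had a ratio over 1. The ratio is not scaled to depth and carries any difference in depth between the libraries. Regions with a low LPS value are missing from it where no LPS interval was called. Where every NT interval had an LPS partner, the SD of the log2 ratio was 0.26 with NT values over 75 and 0.26 with values over 100, and counting error would give 0.26 and 0.23 if each unit of a summit value were 1 independent read.

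**Figure D2:**
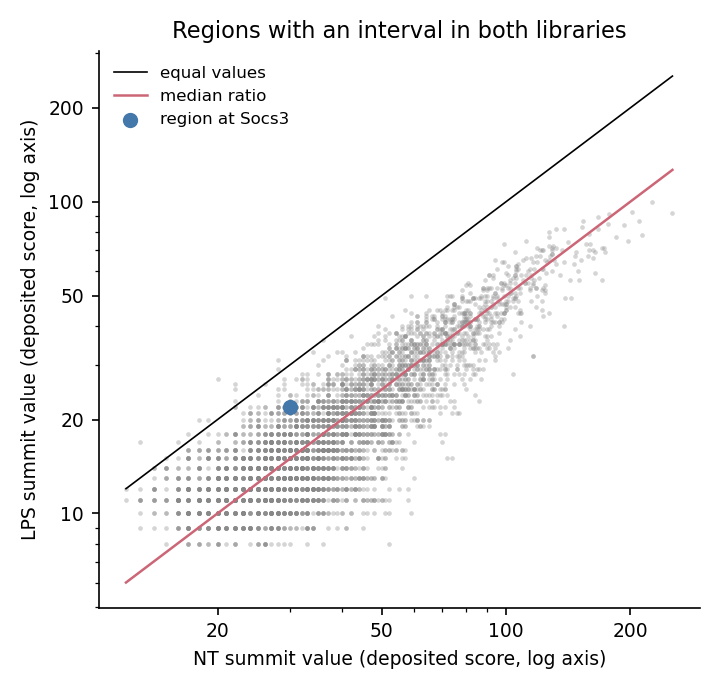
Each point is 1 of the 4027 merged regions with an interval in both libraries, with the NT summit value on the x axis and the LPS summit value on the y axis, both deposited scores on log axes. Most points lie below the line of equal values and around the line of the median ratio of 0.5; the region at Socs3 has values of 30 and 22.

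Among the shared regions at or above the median of the mean summit value, the lowest ratios lay at Elf1 (0.154, summit values 52 in NT and 8 in LPS), Setd5 (0.169), Srd5a3 (0.190), Map2k1 (0.192), Dnajb1 (0.196), Slc16a6 (0.20), Bbc3 (0.203) and Tal1 (0.207). Under the same limit, the highest lay at Nfic (1.11, 28 in NT and 31 in LPS), Fbxo8 (1.04), Sfswap (1.0), Cracd (0.971), B4galnt2 (0.961), a region 885 bp from Pitpnm3 (0.931), a region 13023 bp from Faim (0.897), and Col23a1 (0.893). The ratio of a region need not hold for the whole gene. Within 2.5 kb of their ends, Nfic and Faim had NT intervals (25 and 29) and no LPS interval. The highest values there were 59 and 27 for Pitpnm3 and 34 and 25 for Col23a1. At Fbxo8, Sfswap, Cracd and B4galnt2 the highest values there gave the same ratio as the region. Tal1 encodes a transcription factor of blood stem and erythroid cells, and Map2k1 a kinase of the MAP kinase pathway.

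At the level of genes, 8362 of 21887 protein-coding genes (38.2%) had an NT interval within 2.5 kb of an annotated gene end, and 3536 (16.2%) had an LPS interval. Both libraries had one at 3419 genes, where independent lists of these lengths would share 1351. NT alone had one at 4943 genes and LPS alone at 117. With no interval of the other library within 10 kb, the highest intervals found in NT alone lay at Gemin6 and Srsf7, which share an interval (63), Efcab2 and Urgcp (61), Taf4 (59), and Apbb2, Glce and Apc (58). Under the same limit, the highest found in LPS alone lay at the chemokine genes Ccl4 (24) and Cxcl10 (23), the antiviral gene Rsad2 (21), Lrp11 (20), P3h2 and Nup85 (19), the chemokine gene Ccl5 (18) and Slfn2 (18). With the NT list cut to the length of the LPS list, the gene counts became 1760 for NT alone and 810 for LPS alone.

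Developmental genes carried intervals in both libraries. Of 39 Hox cluster genes, which set positional identity in the embryo, 37 had an NT interval and 34 an LPS interval, against means of 14.9 and 6.27 in random lists (percentile 100 in both). An NT interval from 52210824 to 52237181 on chromosome 6 ran from before Hoxa7 into Hoxa10 with a summit value of 167, and an LPS interval from 52211100 to 52236073 had 82. At Hoxb8 the values were 80 in NT and 44 in LPS. Of 59 developmental transcription factors outside the Hox clusters, 57 had an NT and 55 an LPS interval (percentile 100 in both), among them Tbx2 (162 and 66), Dlx1 (171 and 48) and Nkx2-5 (72 and 48). Of 31 developmental signalling ligands and antagonists, 28 and 26 had one (percentile 100 in both), with Fgf8 at 102 and 56, Gdf7 at 77 and 44, Wnt1 at 71 and 41, and Wnt10a at 62 and 38. No gene of these 3 lists had an LPS interval alone, near the means of 0.20, 0.31 and 0.16 genes in random lists. This absence depends on the longer NT list. Cut to the length of the LPS list, it left 1 Hox gene, 5 developmental transcription factors and 5 developmental signalling genes in LPS alone, and with intervals at or above the median summit value 1 developmental transcription factor was.

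Cell cycle and chromatin genes also had intervals, and over all protein-coding genes 40.9% of those with an NT interval had one in both libraries. Of 7 cyclin-dependent kinase inhibitors, 6 had an NT interval (percentile 99.3) and 4 an LPS interval (percentile 99.0). Cdkn2a, a known polycomb target, had summit values of 47 and 27, Cdkn1c 74 and 35, Cdkn2b 41 and 15, and Cdkn1b 33 in NT with no LPS interval. Of 22 polycomb and related chromatin genes, 14 had an NT interval (percentile 99.1) and 6 an LPS interval (percentile 90.8), and 8 had one in NT alone. With the NT list cut to the LPS length, 5 had an NT interval, 1 in NT alone and 2 in LPS alone. Bmi1 had 198 and 75, Cbx8 150 and 56, and Cbx2 38 and 17.

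**Figure D3:**
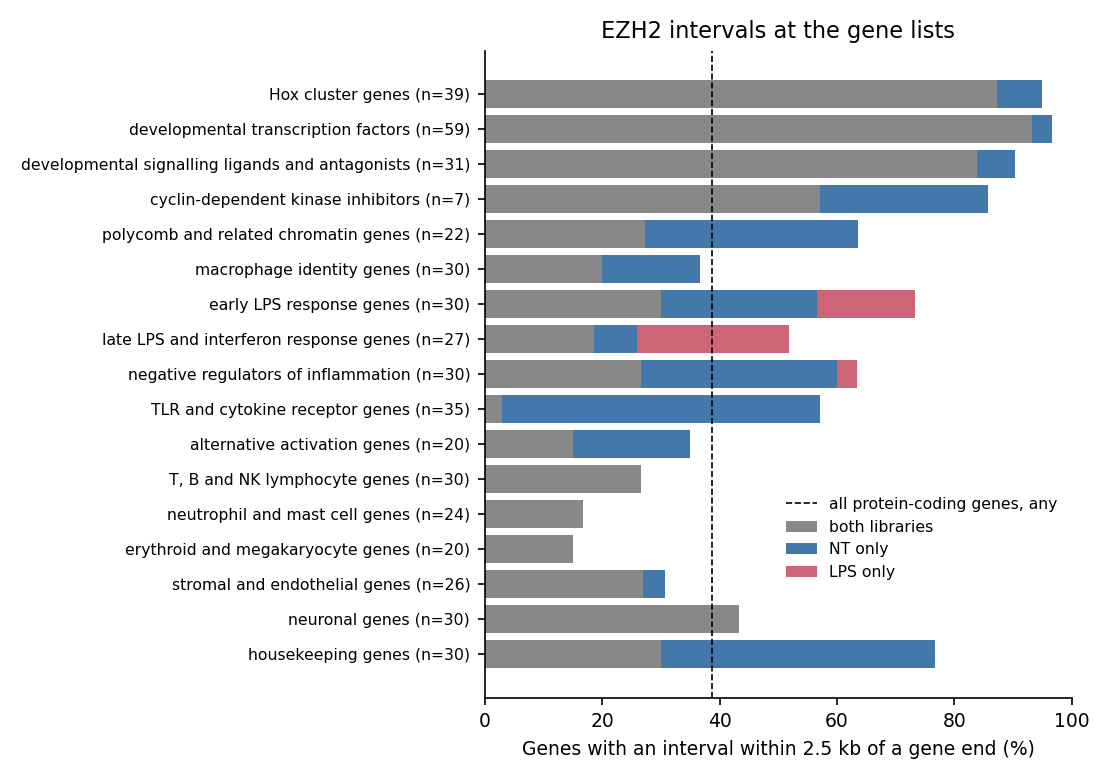
Bars give the percent of each list's n genes with an interval within 2.5 kb of a gene end in both libraries, in NT alone and in LPS alone, and the dashed line gives the share of all protein-coding genes with an interval in either library. Of the 30 early LPS response genes 5, and of the 27 late ones 7, had an interval in LPS alone, while 19 of the 35 TLR and cytokine receptor signalling genes had one in NT alone.

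The question of the study was what LPS does to EZH2 occupancy, and the genes that LPS is known to induce stood apart in intervals found in LPS alone. Of 30 early LPS response genes, 17 had an NT interval (percentile 98.0) and 14 an LPS interval (percentile 100), with 9 in both, 8 in NT alone and 5 in LPS alone. Of 27 late LPS and interferon response genes, 7 had an NT interval (percentile 9.83) and 12 an LPS interval (percentile 99.98), with 5 in both, 2 in NT alone and 7 in LPS alone. Random lists had on average 0.162 and 0.148 genes in LPS alone, and both counts lay at percentile 100. With intervals at or above the median summit value, the counts in LPS alone were 3 early and 3 late genes. The 12 genes of both lists with an interval in LPS alone, given in full after their values were seen, were the early response genes Ccl4 (24), Nfkb1 (17), Tnfaip3 (16), Tnf (14) and Ccl3 (11) and the late response genes Cxcl10 (23), Rsad2 (21), Ccl5 (18), Ifit1 (13), Gbp5 (10), Saa3 (10) and Isg20 (8). They rest on 19 LPS intervals, none of which met an NT interval. These intervals had summit values of 8 to 24 (median 13), and the lowest value in the NT list was 11. At the weakest of them a signal of like value in NT might not have been listed, so these counts can depend in part on the NT threshold. Ccl3 and Ccl4 overlap in the gene table and can share intervals, and an NT interval with a value of 23 lay within 10 kb of Tnf. At Cxcl10 the 2 LPS intervals ran from 92344986 to 92347582 and from 92347650 to 92349226 on chromosome 5. Other genes of these lists had intervals in both libraries, such as Atf3 (33 in NT and 15 in LPS), Zfp36 (33 and 15), Egr2 (47 and 20), Fosb (24 and 13) and Irf1 (39 and 13).

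Signalling genes upstream of this response showed the other distribution. Of 35 TLR and cytokine receptor signalling genes, 20 had an NT interval (percentile 98.9) and 1 an LPS interval (percentile 0.955). With lists matched on gene length the NT count lay at 97.2, inside the central 95%, and with the NT list cut to the length of the LPS list 5 genes had an NT interval and 5 one in NT alone. The gene with an LPS interval was Jak1 (24 in NT and 13 in LPS), while Rela (26), Tlr9 (23) and Cd14 (20) had NT intervals alone. The median NT summit value of the list's genes with an NT interval was 23.5, in the range where few NT intervals had an LPS partner. Of 30 negative regulators of inflammatory signalling, 18 had an NT interval (percentile 99.2) and 9 an LPS interval (percentile 96.9), with 10 in NT alone and 1 in LPS alone, or 5 and 2 with the NT list cut. Socs2 had 89 and 31, and Socs1 35 and 18.

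Socs3, which encodes a feedback inhibitor of cytokine signalling, lies on chromosome 11 from 117966079 to 117970336 (mm10). The NT interval over the gene, from 117967218 to 117969673, had a summit value of 30, and the LPS interval from 117967375 to 117970158 had 22. Their ratio of 0.733 lay above 94.1% of the shared regions, and 62 of 1226 regions with an NT value within 5 of that at Socs3 had a ratio as high or higher. With 1 library per condition and the unit of the values unknown, the error of this ratio is not known. A second LPS interval, from 117965014 to 117966112 with a value of 13, met the lower-coordinate end of the gene and no NT interval. An NT interval with a value of 18 lay 1809 bp from the gene and met no LPS interval.

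**Figure D4:**
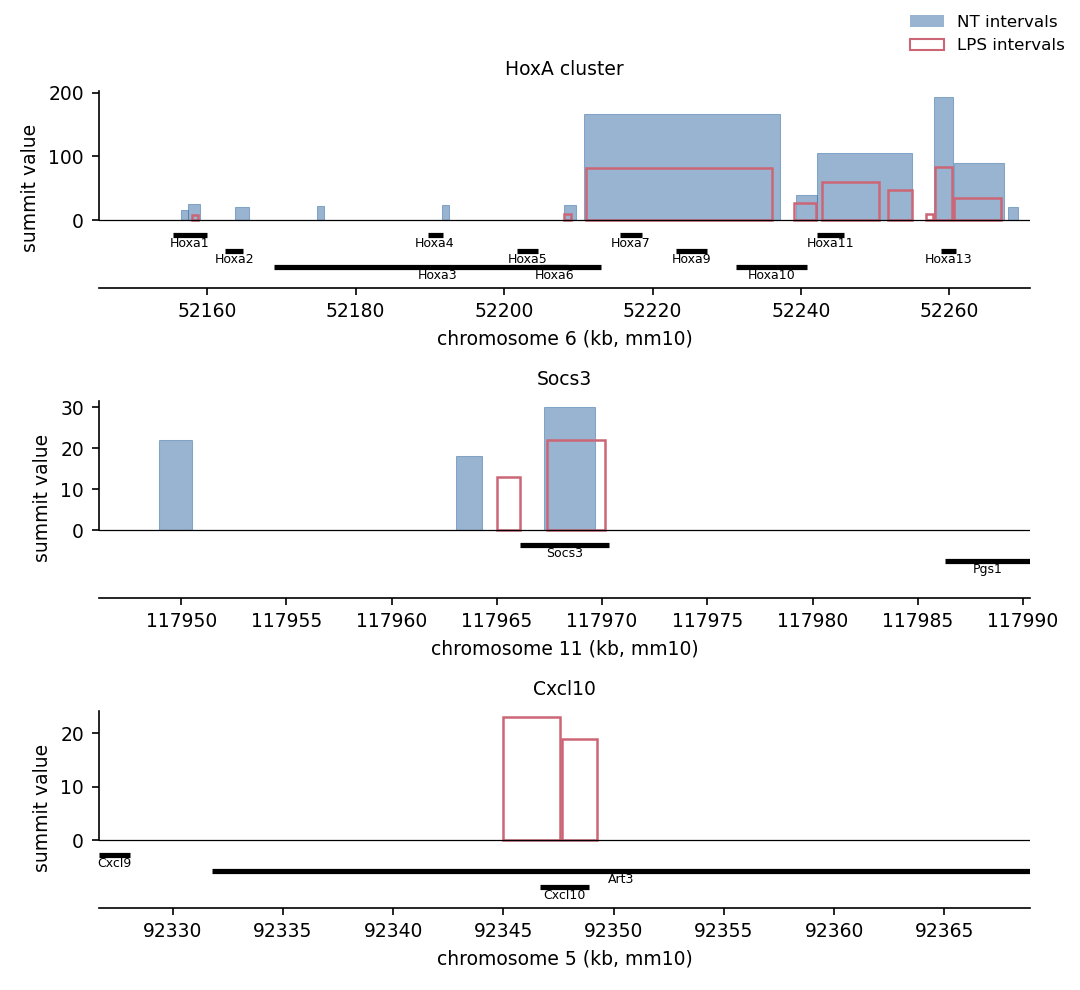
Intervals of NT (filled) and LPS (outlined) are drawn to scale along chromosomes 6, 11 and 5 in kb of mm10, with their summit value as height and protein-coding genes as black bars. Both libraries have an interval from before Hoxa7 into Hoxa10 (167 and 82), Socs3 has an interval in both and a further LPS interval with a value of 13, and Cxcl10 has LPS intervals with values of 23 and 19 and none of NT.

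Macrophage genes were near the level of random lists. Of 30 macrophage identity genes, 11 had an NT interval (percentile 43.6) and 6 an LPS interval (percentile 71.7). The transcription factor gene Junb had values of 67 and 25, Fos 46 and 12, and Cebpa 33 and 15. Of 20 alternative activation genes, 7 and 3 had one (percentiles 38.7 and 46.95), with Klf4 at 37 and 14, Fn1 at 21 and 11, Kdm6b at 17 and 8, and Irf4 at 18 in NT alone.

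Genes of other cell types with an NT interval had, with 1 exception among the stromal and endothelial genes, an LPS interval too. The counts were 8 of 30 for T, B and NK lymphocyte genes in NT and also in LPS (percentiles 9.45 and 93.2), 4 of 24 for neutrophil and mast cell genes (1.38 and 54.3), 3 of 20 for erythroid and megakaryocyte genes (1.52 and 47.1) and 13 of 30 for neuronal genes (71.3 and 99.99). With lists matched on gene length, the NT counts of neutrophil and of erythroid genes lay at 6.86 and 4.74, inside the central 95%. Of 26 stromal and endothelial genes, 8 had an NT and 7 an LPS interval (22.5 and 92.0). In the order given, the median NT summit values of genes with an NT interval were 52, 56.5, 58, 56 and 77.5, where nearly all NT intervals had an LPS partner. Among genes matched on summit value and width, the counts in both lay at 93.6, 71.6, 62.4, 83.1 and 56.5, inside the central 95%. Matched on summit value alone, lymphocyte (98.6) and neuronal genes (98.8) lay outside, as did lymphocyte genes with matched intervals (99.1). Members with intervals included the transcription factor genes Tbx21 (124 in NT and 54 in LPS), Lef1 (78 and 33), Gfi1 (82 and 43), Gata2 (72 and 45) and Sp7 (108 and 51), and the neuronal transporter genes Slc32a1 (98 and 53) and Slc17a7 (57 and 45).

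Housekeeping genes, which are transcribed in every cell, also had intervals. Of 30 such genes, 23 had an NT interval (percentile 100) and 9 an LPS interval (percentile 97.0, or 98.8 with lists matched on gene length), with 14 in NT alone. Eef1a1 had values of 54 and 16, Actb 46 and 25, and Hsp90ab1 33 and 11. The median NT summit value over the list's genes with an NT interval was 37. Taken in the same way it was 80 for the Hox cluster genes and 58 for the developmental transcription factors.

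Most intervals of both libraries lay at gene ends. The midpoint was within 2.5 kb of an annotated end of a protein-coding gene for 78.2% of NT intervals (95% Wilson interval 77.3 to 79.0%) and 74.0% of LPS intervals (72.7 to 75.2%), against 7.56% of random positions for each. Inside genes lay 13.5% of NT and 15.8% of LPS intervals, against 37.0% and 36.6% of random positions. Between genes lay 8.34% and 10.3%, against 55.4% and 55.8%.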

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

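Random lists matched on gene length, gene families and the matchings on summit value and width were chosen after the data were seen; all other alternatives were fixed before the data were examined. No paired analysis was possible because each condition had 1 library. Alternatives that need strand, exons, sequence or promoter CpG content were not run. With 1 library per condition and unknown depth, the values below show dependence on the settings and not on the biological samples. Of 592 recomputed values, 476 stayed close to the reported one (counts within 1.5 times, shares inside their interval, percentiles on the same side of the central 95% of random lists) and 116 did not. The cause was not tested, except that stricter settings use fewer intervals by construction.

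With intervals at or above the median summit value, 4830 NT and 2511 LPS intervals were left and NT covered 11084.4 kb. NT was met at 64.0% and LPS at 98.9%. Genes at an interval numbered 4662 in NT, 2135 in LPS, 2021 in both and 2641 in NT alone. NT counts were 10 for early LPS, 3 for late LPS, 5 for TLR signalling, 5 for polycomb, 7 for macrophage identity and 2 for alternative activation genes. LPS counts were 8 for early LPS, 4 for late LPS, 0 for TLR signalling, 2 for macrophage identity, 0 for alternative activation and 4 for housekeeping genes. Counts in NT alone were 5 for early LPS and TLR signalling genes, 2 for alternative activation and neuronal genes, and 1 for Hox, developmental transcription factor, polycomb, lymphocyte, neutrophil and erythroid genes. Counts in LPS alone were 3 for early and 3 for late LPS genes and 1 for developmental transcription factors. Gene ends held 81.2% of NT and 77.2% of LPS intervals, and 5.71% and 6.97% lay between genes.

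With the NT list cut to the LPS length, NT was met at 65.6% and LPS at 71.4%, and genes numbered 4486 in NT, 1760 in NT alone and 810 in LPS alone. NT counts were 10 for early LPS, 3 for late LPS, 5 for TLR signalling, 5 for polycomb, 7 for macrophage identity and 2 for alternative activation genes. Counts in NT alone were 5 for TLR signalling and negative regulator genes, 2 for early LPS and macrophage identity genes, 1 for late LPS, developmental transcription factor, developmental signalling, kinase inhibitor, polycomb and alternative activation genes, and 0 for Hox and stromal genes. Counts in LPS alone were 5 for developmental transcription factors and 5 for developmental signalling genes, 2 for polycomb, negative regulator and alternative activation genes, and 1 for Hox, macrophage identity, TLR signalling, lymphocyte and housekeeping genes, so an interval in LPS alone depends on the NT threshold for these lists.

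With 1 kb windows, 6 Hox and 1 late LPS gene were in NT alone, gene ends held 65.2% of NT and 55.2% of LPS intervals, 25.1% and 31.8% lay inside genes and 9.70% and 13.0% between them. With 5 kb windows, 6 erythroid genes had an NT interval, and 2 erythroid, 1 lymphocyte and 1 developmental transcription factor gene were in NT alone. With the gene body, 1 developmental transcription factor, 1 lymphocyte and 1 erythroid gene were in NT alone and 1 developmental signalling gene in LPS alone. With at least 50% of the interval covered, NT was met at 40.1% and LPS at 93.0%. Within 50 kb of Socs3 there were 4 NT intervals.

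Of the percentiles, 5 of 30 entered or left the central 95% of random lists with lists matched on gene length, 9 of 53 with genes matched on summit value and width, 6 of 53 with intervals matched on both, and 3 of 28 with each of 2 finer matchings of intervals.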

Other observations

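All tests and gene families in this part were chosen after the fixed lists had been examined; of the explanations weighed, the 2 tests on ribosomal protein genes were written down before their values were seen, and the tests on developmental transcription factor genes, on NT intervals over 75, on the summit ratio, on random placement, on broad and narrow intervals and on interval width were chosen only after the result was seen.

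Gene families defined by symbol alone separated further. Over all protein-coding genes, 38.2% had an NT interval and 16.2% an LPS interval. No interval of either library lay at the 1106 olfactory receptor genes, and 1 NT interval lay at the 353 vomeronasal receptor genes (16), both families of chemical senses. Sox genes (17 of 19 in NT and 16 in LPS), Wnt genes (17 and 16 of 19), Fox genes (35 and 27 of 44), Tbx genes (9 and 7 of 13) and voltage-gated potassium channel genes (25 and 22 of 40) had intervals in both libraries. Ribosomal protein genes had 55 and 20 of 81, proteasome subunit genes 23 and 4 of 39, mitochondrial complex I genes 20 and 3 of 37, and splicing factor Srsf genes 9 and 1 of 11. Keratin genes had 3 and 2 of 49, and zinc finger genes with Zfp symbols 131 and 42 of 367.

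On the X chromosome 12.5% of 966 protein-coding genes had an NT interval and 3.93% an LPS interval, against 39.9% and 16.9% of 20665 autosomal genes. The median NT summit value of the genes with an interval was 21 on X and 28 on autosomes. No explanation was tested for this difference.

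The first pattern weighed is the 5482 NT intervals with no LPS interval. A threshold acting on weak NT intervals is open, since 100% of NT intervals over 75 met an LPS interval. For 1 lower signal factor in all regions, the test written beforehand used the LPS count of ribosomal protein genes. That count lay at percentile 24.0 of lists matched on NT summit value, inside the central range. The ratio of summit values of these genes, not part of that test, lay outside it with the same matching (0.28). It lay inside with genes matched on width too (3.83) and with intervals matched on both (2.51). The limit on matching given next holds for these values as well. NT intervals at developmental transcription factor genes met LPS intervals at percentile 100 of intervals matched on summit value and width. This does not decide against the factor, because a single NT summit value carries counting error. The intervals at these genes had a median NT summit value of 42.5, against 27 over all NT intervals. At a like observed value their underlying signal can be higher, so more of them can meet LPS intervals under 1 factor as well. Broad and narrow NT intervals of like summit value also differed, as over 50 and up to 75 the median ratio was 0.393 under 2 kb and 0.5 at 2 kb or wider. The same limit holds for this comparison. The SD of the log2 ratio was near counting error for NT values over 75 (0.26 against 0.26) and above it over 100 (0.26 against 0.23), if each unit were 1 independent read. NT intervals over 75 were broad, with a median width of 4510.5 bp against 1305 bp over all NT intervals. Their spread therefore does not weigh on 1 factor in narrow or weak regions. Less EZH2 on chromatin after LPS cannot be told apart from lower depth, as the median ratio of 0.5 is not scaled to any depth, input or spike-in.

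That comparison was 1 of several, as 3 matchings, and later 2 finer ones, were tried in turn on 30 lists and families, all but the first after the values of the first were seen. For LPS intervals at NT genes, 28 lists and families were large enough. Outside the central 95% of random lists lay 10 with genes matched on summit value, 4 with genes matched on summit value and width, and 8 with intervals matched on both. The nominal rate would put 1.4 outside. It takes the members of a list as independent, although neighbouring genes share intervals, and matched counts were not simulated, so it may be too low. Outside in all 3 were developmental transcription factors (100, 99.9 and 100), developmental signalling genes (99.97, 99.7 and 99.9) and potassium channel genes (99.995, 99.5 and 99.7). Finer classes of summit value and width, tried last, left developmental transcription factors at 99.99 and 100; the shape of the signal within an interval was not matched. TLR and cytokine receptor signalling genes were outside in the first and the third (0.60, 6.01 and 2.33) and inside with the finer classes (2.92 and 3.51), so whether low NT values and narrow intervals account for their near absence from LPS is left open. Ribosomal protein genes were at 24.0, 89.9 and 68.8. For the ratio of summit values, 7, 4 and 5 of 25 were outside, against 1.25 at the nominal rate. That rate may be too low, since 4 of 40 null lists lay outside in the simulated matched medians, whose setting differed from these data. In all 3 matchings 4 were outside, namely macrophage identity genes (0.42, 0.38 and 0.78), late LPS and interferon genes (0.47, 0.48 and 1.61), polycomb genes (2.07, 2.02 and 1.18) and Zfp genes (1.62, 2.35 and 1.39). These ratios rest on 6, 5, 6 and 38 genes with an interval in both libraries. Ribosomal protein genes (0.28, 3.83 and 2.51) and housekeeping genes (0.835, 5.9 and 3.68) were outside only in the first, developmental transcription factors (99.98, 96.98 and 99.85) in the first and the third, and lists that share genes are not independent.

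The second pattern weighed is the LPS-only intervals at LPS-induced genes, where 12 of 57 early and late genes had an interval in LPS alone against 0.303 in random lists. Random placement is argued against by percentile 100 of that count. The count can depend in part on the NT threshold. The 19 LPS intervals at these genes had summit values of 8 to 24, and the lowest NT value was 11. Signal that does not depend on the antibody at strongly transcribed genes is a candidate explanation, since ribosomal protein genes, also strongly transcribed, had NT intervals at percentile 100 of random lists. In LPS, ribosomal protein genes were at 97.7 and housekeeping genes at 97.0. Proteasome subunit, mitochondrial complex I and splicing factor Srsf genes were at 99.5, 97.4 and 99.8 in NT, but at 15.9, 8.5 and 30.2 in LPS. Macrophage identity genes, which these cells are known to transcribe, were at 43.6 in NT and 71.7 in LPS. Transcription was not measured and CpG content was not analysed here. EZH2 recruited to induced genes by LPS stays open as a hypothesis, as neither intervals of the input nor cells without EZH2 were used here. Recruitment was taken to predict intervals as wide as those at developmental genes. That was not met, as the median widest LPS interval was 1167 bp at these 12 genes and 4466 bp at developmental transcription factors, and the median bases covered were 1993 and 4501. Width still does not decide on recruitment, since part of the gap went with the lower summit values at these 12 genes. Bases covered were added after the widest intervals were seen, as was a range of like summit value, in which the gap was smaller. Over LPS intervals with summit values of 8 to 24 the median widths were 1141 and 1599 bp, with 1083 bp at housekeeping and 995.5 bp at ribosomal protein genes.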
